A study of Saccharomyces cerevisiae with 70 samples.

How the data were processed

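RNA of synchronised budding yeast was measured on 70 arrays of 3 types in 4 time courses, 2 with hydrogen peroxide and 2 with menadione. Per the labels, the synchronised sample carried Cy5 and an asynchronous reference culture carried Cy3. The values were taken as log2 ratios of sample to reference as the authors deposited them, with spot filter, background correction and normalisation not stated. Neither the log base nor the centring nor the direction of the ratio is stated. Base 2 was an assumption for values of both signs, and it was not tested. The direction was judged from the mating pheromone list at 0 min, whose mean log2 ratio was positive in all 4 courses, at 1.30 in menadione I, 0.98 in peroxide I, 1.67 in peroxide II and 1.70 in menadione II.

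The table of menadione I held 13056 probes on 14 arrays, that of peroxide I 9984 probes on 23 arrays and that of the second series 14976 probes on 33 arrays. Of these probes 9565, 6625 and 6570 named 1 gene in the annotation, none named several, and 3491, 3359 and 8406 were not in it and were left out of the comparisons. Gene symbols were updated through gene identifiers for 9555, 6620 and 6565 probes. Probes of a gene were averaged, each array was centred on the median of its genes, and arrays repeated at 1 time of peroxide I (20 and 63 min) were averaged. Before centring, array medians over genes ran from -0.058 to 0.29 in menadione I, from -0.21 to 0.22 in peroxide I and from -0.55 to 0.22 in the second series. Missing spots took 6.3% to 14.5%, 4.1% to 10.7% and 1.2% to 26.9% of an array. The lowest correlation between a pair of arrays over genes was 0.118 in menadione I, -0.303 in peroxide I and 0.137 in the second series. The pair at 20 min of peroxide I correlated at 0.127 over 5532 genes and that at 63 min at 0.407 over 5458. Means of the gene lists described below differed by a median of 0.23 within the 20 min pair, and at most by 0.95. For the 63 min pair these values were 0.313 and 1.73. The mean of the 20 min pair is 1 of the 3 baseline points of every peroxide I change, and a wrong time label or a failed hybridisation is not excluded. With the first arrays of the pairs alone 29 and 868 genes changed at 22 to 50 and 51 to 90 min of peroxide I, and with the redo arrays alone 57 and 791. The 49 min array, labelled a redo without a partner, was kept in both. No column was left without a sample. For arrays the number of arrays limits the precision, and signal over background was not given in the files used here.

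Times were grouped into the first 21 min, 22 to 50 min, 51 to 90 min and after 90 min. Genes needed a value in 75% of the arrays of the table and in at least 2 arrays of each group compared. A linear model with 1 mean per group and course was fitted in limma 3.58.1 under R 4.3.3, with moderated variances and with each contrast as a coefficient of an equivalent model. The 13 comparisons were each window against the first 21 min in both courses of the second series, the difference between their changes as an interaction, and the 22 to 50 and 51 to 90 min windows of the first series. P-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a threshold of 0.05. The residual spread was pooled over all windows of an array table, and in the second series over both courses. Because each course is 1 culture, p-values measure this pooled spread between time points within windows only. It holds real change over time and technical noise alike, and p-values carry no spread between cultures.

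For 26 gene lists, camera compared members with all other genes at a preset correlation of 0.01 and again with a correlation estimated from the residuals around the window means, adjusted over the lists of a comparison. The lists, windows, tests, the rule for named genes and all alternatives but the added ones were fixed before the data were examined. Named genes were up to 10 of the largest rises and falls past the threshold at 22 to 50 min of the second series, with the same sign in the first-series course of that agent, and up to 10 each in the differences. To these came 38 genes named whatever their values, and up to 4 members per list with the largest absolute change. Differences between agents come from the interaction alone, and the first series was not compared with the second by a test.

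Scan days are confounded with part of the design. Of the 17 peroxide II arrays, 14 were scanned on 1 day, and those of 14, 21 and 28 min on another. The menadione II arrays were scanned on a day of their own, so that day and agent cannot be separated for the level of a gene, while the change from the first 21 min is taken within a course. The scan day of the peroxide II arrays was tried as a covariate, and, chosen after the data were seen, each day was fitted on its own. On the first day the peroxide II baseline is 0 and 7 min alone, so that fit changes the baseline times along with the scan day.

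The method was tested on simulated data, in a test written after the first fit to the real values. Each gene had independent normal noise of its own spread, with the missing values of its table and 200 changed genes per comparison. Of genes changed by a log2 of 1, 2 and 3, it recovered 17.9%, 62.7% and 90.9% in peroxide II at 22 to 50 min, with 9 false calls of 123. For the difference at 22 to 50 min these were 3%, 26.9% and 78.8% (3 false of 75), and for the difference after 90 min 3%, 38.8% and 66.7% (4 false of 76). In peroxide I at 51 to 90 min they were 53.7%, 92.5% and 98.5% (13 false of 176), and in menadione I 6%, 58.2% and 84.8% (5 false of 104). A list shifted by 1 was called in each of these comparisons, and none of the 25 other lists was, though the simulated genes were not correlated. Alternatives covered the centring and scaling of arrays, the filter, variance moderation, array weights, the baseline, the window edges, the arrays that share the spread, the scan day, shared times, single probes, repeated arrays, list tests and each array left out.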

Results

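Responses of budding yeast to 2 oxidants were followed over time on 2-colour arrays, in 4 courses of synchronised cells and on 70 arrays in all. One oxidant was hydrogen peroxide, and the other was menadione, a quinone that cycles between reduced and oxidised forms inside the cell and makes superoxide. The deposited log ratios are taken here as log2, since neither their base nor their direction is stated. On each array the Cy5-labelled RNA of the synchronised culture at 1 time was set against Cy3-labelled RNA of an asynchronous culture, the common reference. In the first series, peroxide I (0.24 mM, 23 arrays at 21 times from 0 to 275 min) and menadione I (2 mM, 14 arrays from 0 to 210 min) were hybridised to arrays of different design. In the second series, peroxide II (17 arrays, 0 to 180 min) and menadione II (16 arrays, 0 to 140 min) used strain DBY8724 and 1 array design, and the labels give times after release from G1 arrest but no dose. The labels used here name neither the time at which the oxidant was added nor an untreated course. Each comparison therefore sets the mean log2 ratio of a window (22 to 50 min, 51 to 90 min or after 90 min) against the first 21 min of the same course, and a change holds the progress of the released cells through the cycle as well as the response to the oxidant. Between 1.2% and 26.9% of spots per array had no value, and the number of time points per window, 2 to 10, limits the precision. Gene changes are log2 differences ± SE with the Benjamini-Hochberg adjusted p of limma, and gene list changes are means over members ± SE over genes with the adjusted p of camera. Each course was 1 culture, so its time points stand in for replicates.

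The first comparison asked how cells changed early in the peroxide course. In peroxide II at 22 to 50 min, mRNAs of several oxidant defence genes rose. CCP1, the mitochondrial cytochrome c peroxidase, rose by 4.79 ± 0.89, adjusted p = 0.00176 (4 arrays against 4), and PRX1, the mitochondrial peroxiredoxin, by 3.84 ± 0.63, adjusted p = 0.000419. The thioredoxin reductase gene TRR1 rose by 3.40 ± 0.62, adjusted p = 0.00131, the thioredoxin gene TRX2 by 2.02 ± 0.54, adjusted p = 0.0293 and the peroxiredoxin gene TSA2 by 4.13 ± 0.81, adjusted p = 0.00312. The drug exporter gene FLR1 rose by 4.04 ± 0.65, adjusted p = 0.000419, and ECM4, of the glutathione transferase family, by 4.61 ± 0.90, adjusted p = 0.003. In the same window AGA2, an agglutinin subunit of mating, fell by 3.93 ± 0.59, adjusted p = 0.000191. DSE2, a daughter-specific wall protein gene, fell by 5.12 ± 1.11, adjusted p = 0.00654.

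Of 5501 genes tested, 217 changed in this window, 152 up and 65 down. Fitted with the arrays of these 2 windows alone the count was 15, and with other window edges 85. Of 35 splits of the arrays 4, the real one among them, gave as many genes (highest other 386), so chance is not excluded for the count. The splits with 386, 320 and 262 genes put 28 min with early arrays. They kept much of the change over time and cannot decide about chance. Among the 23 measured Yap1 and thiol-redox genes, 13 rose and none fell, against 19 higher and 1 lower when adjusted over the list alone. The list mean was 2.20 ± 0.30 (adjusted p = 6.9e-19, and adjusted p = 0.00652 with an estimated correlation). Outside that list GRE2, a methylglyoxal reductase gene, rose by 4.07 ± 0.59, adjusted p = 0.000191 and OSI1 by 5.30 ± 0.84, adjusted p = 0.000419. AAD15, an aryl-alcohol dehydrogenase gene, rose by 3.91 ± 0.80, adjusted p = 0.0044 and YMR027W by 4.46 ± 0.55, adjusted p = 1.41e-05. CYC1, for iso-1-cytochrome c, rose by 3.65 ± 0.67, adjusted p = 0.00131 and LYS20, for homocitrate synthase, by 3.00 ± 0.49, adjusted p = 0.000419. ISU2, an iron-sulfur scaffold gene, rose by 3.33 ± 0.55, adjusted p = 0.000433 and ZWF1, for glucose-6-phosphate dehydrogenase, by 2.56 ± 0.52, adjusted p = 0.00374. PUP3, a proteasome core subunit gene, rose by 3.70 ± 0.83, adjusted p = 0.00917. Of the 33 proteasome genes 3 rose, 4 when adjusted over the list alone, and the list mean was 0.61 ± 0.13 (adjusted p = 0.000322, and adjusted p = 0.235 with an estimated correlation). Of the 35 general stress genes, 2 rose, DDR2 among them at 4.20 ± 1.06, adjusted p = 0.0211, and 11 were higher when adjusted over the list alone. The list averaged 0.94 ± 0.17 (adjusted p = 0.000147, and adjusted p = 0.316 with an estimated correlation).

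Ribosome biogenesis genes had a mean of -0.85 ± 0.15 (adjusted p = 3.2e-06, and adjusted p = 0.218 with an estimated correlation). Of the 40 members 4 fell, with 7 lower and 1 higher when adjusted over the list alone. BRX1 fell by 2.27 ± 0.56, adjusted p = 0.0178 and NSR1 by 2.62 ± 0.75, adjusted p = 0.0437. No cytosolic ribosomal protein gene of 72 passed limma's test, over all genes or adjusted over the list alone, while 1079 of all genes had an unadjusted p under 0.05. Of the 72 genes 62 had a negative value, and the list mean was -0.45 ± 0.065 (adjusted p = 1.16e-05, and adjusted p = 0.259 with an estimated correlation). Mating pheromone genes had a mean of -1.17 ± 0.20 (adjusted p = 7.33e-09, and adjusted p = 0.129 with an estimated correlation). Of the 25 members 4 fell, 9 when adjusted over the list alone. MFA2, for a-factor, fell by 3.14 ± 0.66, adjusted p = 0.0045 and GIC2 fell by 1.94 ± 0.39, adjusted p = 0.00391. Of cell cycle genes, the G1 cyclin gene CLN2 fell by 2.37 ± 0.60, adjusted p = 0.0218 while the mitotic cyclin gene CLB2 rose by 2.03 ± 0.42, adjusted p = 0.00417. SCW11, of the SIC1 cluster expressed from late mitosis to G1, fell by 2.49 ± 0.51, adjusted p = 0.00417. SPO12, of the CLB2 cluster of G2/M genes, fell by 1.72 ± 0.40, adjusted p = 0.0106, and the mean of the 30 cluster genes was 0.025 ± 0.16 (adjusted p = 0.86). Further lists shifted in this window with the preset correlation alone. Iron uptake genes averaged 0.85 ± 0.21 (adjusted p = 0.00071, and adjusted p = 0.195 with an estimated correlation), and heat shock chaperone genes 0.58 ± 0.15 (adjusted p = 0.0182, and adjusted p = 0.345 with an estimated correlation). The SIC1 cluster averaged -1.02 ± 0.33 (adjusted p = 0.00184, and adjusted p = 0.195 with an estimated correlation). G1/S genes stood at -0.37 ± 0.11 (adjusted p = 0.0315, and adjusted p = 0.388 with an estimated correlation).

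The peroxide II arrays were scanned on 2 days, with the arrays of 14, 21 and 28 min on the second. Within the first day, whose baseline arrays were those of 0 and 7 min only, 328 genes changed and the Yap1 list mean was 2.54. Within the second day, whose only later array was that of 28 min, 10 genes changed and the Yap1 list mean was 0.79 (adjusted p = 0.0526). Because 1 array stands for the later window there, these values weigh neither for nor against an effect of scan day. With scan day as a covariate 126 genes changed. Leaving out single arrays gave 122 genes without 14 min, 696 without 28 min, 69 without 42 min and 81 without 49 min.

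At 51 to 90 min of peroxide II, genes of oxidant defence were up and ribosomal protein mRNAs had fallen. FLR1 was up by 4.57 ± 0.65, adjusted p = 4.02e-05 (4 arrays against 4), ECM4 by 5.86 ± 0.90, adjusted p = 0.000113, CCP1 by 5.16 ± 0.89, adjusted p = 0.000339 and TRR1 by 3.99 ± 0.62, adjusted p = 0.000113. In all 19 of the 23 list members rose, also 19 when adjusted over the list alone. The list averaged 2.75 ± 0.34 (adjusted p = 1.82e-20, and adjusted p = 0.00364 with an estimated correlation). The gene of the transcription factor Yap1 itself, YAP1, rose by 2.28 ± 0.60, adjusted p = 0.0109, and GSH1, for the first step of glutathione synthesis, by 3.05 ± 0.77, adjusted p = 0.00818. Of the 72 cytosolic ribosomal protein genes 38 fell, 50 when adjusted over the list alone. RPL9A fell by 2.28 ± 0.38, adjusted p = 0.000211 and RPL43A fell by 2.18 ± 0.40, adjusted p = 0.000544, with a list mean of -1.16 ± 0.083 (adjusted p = 5.89e-23, and adjusted p = 0.00364 with an estimated correlation). Of 5519 genes tested, 774 changed, 496 up and 278 down.

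General stress genes made up a second group that rose at 51 to 90 min, 17 of 35 and 20 when adjusted over the list alone. Among them TFS1 rose by 5.22 ± 0.88, adjusted p = 0.000254, DDR2 by 5.19 ± 1.06, adjusted p = 0.00169 and the nicotinamidase gene PNC1 by 3.36 ± 0.76, adjusted p = 0.00341. On average they stood at 1.66 ± 0.25 (adjusted p = 4.49e-09, and adjusted p = 0.132 with an estimated correlation). Of the 21 measured iron regulon genes 8 rose, 12 when adjusted over the list alone. The cell wall mannoprotein genes FIT3 and FIT2 rose by 3.49 ± 0.63, adjusted p = 0.000444 and 2.84 ± 0.71, adjusted p = 0.00715. The mean change was 1.38 ± 0.24 (adjusted p = 9.99e-07, and adjusted p = 0.0225 with an estimated correlation). Of the proteasome genes 11 of 33 rose, 14 when adjusted over the list alone. RPN1 rose by 2.20 ± 0.36, adjusted p = 0.000165 and RPT2 by 2.16 ± 0.44, adjusted p = 0.00142. The mean was 1.03 ± 0.14 (adjusted p = 4.3e-07, and adjusted p = 0.0975 with an estimated correlation). Autophagy and vacuolar genes rose in 6 of 15 cases, 7 when adjusted over the list alone. ATG8 rose by 1.52 ± 0.49, adjusted p = 0.0362 and APE1 by 3.60 ± 0.77, adjusted p = 0.00218. Their mean was 0.91 ± 0.27 (adjusted p = 0.0186, and adjusted p = 0.132 with an estimated correlation). The ribosome biogenesis list averaged -1.07 ± 0.19 (adjusted p = 2.04e-07, and adjusted p = 0.132 with an estimated correlation). Of its 40 genes 13 fell and 2 rose, 19 and 2 when adjusted over the list alone. DBP2 fell by 3.20 ± 0.59, adjusted p = 0.000533 and MRT4 fell by 3.51 ± 0.69, adjusted p = 0.00124, whereas RLP24 rose by 2.67 ± 0.73, adjusted p = 0.0133. RNR2, a small subunit gene of ribonucleotide reductase, rose by 2.98 ± 0.61, adjusted p = 0.00169, the large subunit gene RNR1 by 1.93 ± 0.64, adjusted p = 0.0397 and CLB2 by 2.14 ± 0.42, adjusted p = 0.00107. CTS1, for endochitinase of cell separation, fell by 3.74 ± 1.06, adjusted p = 0.0174 and MFA1 fell by 3.07 ± 0.53, adjusted p = 0.00029.

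Within the first scan day, to which all arrays of this window belonged, 365 genes changed, and 202 with scan day as a covariate. The means of the Yap1 and ribosomal protein lists were 2.29 and -1.03 with the covariate. Leaving out the 56 min array left 495 genes.

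After 90 min of peroxide II, 35 of 5520 genes differed from the first 21 min, 28 up and 7 down. CLB2 was higher by 2.53 ± 0.40, adjusted p = 0.00106 (5 arrays against 4), RNR2 by 3.01 ± 0.58, adjusted p = 0.00778 and its partner RNR4 by 2.66 ± 0.51, adjusted p = 0.00778. The mating gene MFA1 fell by 3.68 ± 0.50, adjusted p = 0.00013 and AGA2 fell by 2.41 ± 0.56, adjusted p = 0.0314. CCP1 (4.56 ± 0.86, adjusted p = 0.00778) and PRX1 (2.76 ± 0.60, adjusted p = 0.0213) stayed high, while FLR1 was at 0.15 ± 0.61, adjusted p = 0.957. Of the 23 Yap1 list members 4 were higher, 9 when adjusted over the list alone. The list averaged 1.14 ± 0.25 (adjusted p = 3.67e-07, and adjusted p = 0.121 with an estimated correlation). Of the 13 DNA damage genes the 2 RNR genes rose, also 2 when adjusted over the list alone, and the list mean was 0.83 ± 0.27 (adjusted p = 0.00111, and adjusted p = 0.0851 with an estimated correlation). Within the first scan day 22 genes changed, and 6 with scan day as a covariate. Leaving out the array of 7, 100, 120 or 140 min gave 57, 17, 16 and 16 genes. Counts were 126 with arrays scaled to the same spread, 83 with the deposited values as given, 64 with array weights and 20 with the arrays of these 2 windows alone.

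The same windows were then examined with menadione. At 22 to 50 min of menadione II, no single gene of 5538 passed limma's test (smallest adjusted p = 0.0983, with 444 genes at an unadjusted p under 0.05 where chance gives 276.9), but genes of the CLB2 cluster shifted up together. Their mean was 0.68 ± 0.14 over 30 genes, 24 of them positive (adjusted p = 4.98e-07, and adjusted p = 0.0047 with an estimated correlation), and 6 were higher when adjusted over the list alone. The bud site gene BUD3 was at 2.00 ± 0.43, adjusted p = 0.0983 and the mitotic cyclin gene CLB1 at 1.57 ± 0.35, adjusted p = 0.0983 (4 arrays against 4). Sulfur amino acid genes had a mean of 0.54 ± 0.15 over 22 genes (adjusted p = 0.000362, and adjusted p = 0.0047 with an estimated correlation). When adjusted over the list alone 2 of them were higher, and MET3, for ATP sulfurylase, was at 1.89 ± 0.46, adjusted p = 0.0983. The Yap1 and thiol-redox list had a mean of 0.92 ± 0.16 (adjusted p = 1.08e-07, and adjusted p = 0.111 with an estimated correlation). Of its 24 genes 5 were higher when adjusted over the list alone, with GPX2 at 2.52 ± 0.63, adjusted p = 0.0993 and PRX1 at 2.41 ± 0.64, adjusted p = 0.126. Histone genes had a mean of 1.16 ± 0.30 (adjusted p = 0.00103, and adjusted p = 0.248 with an estimated correlation), 3 higher and 1 lower of 9 when adjusted over the list alone. Mating pheromone genes had a mean of -0.77 ± 0.16 (adjusted p = 3.92e-07, and adjusted p = 0.111 with an estimated correlation), 4 of 25 lower when adjusted over the list alone. Leaving out the 28 min array gave 10 genes, and 21 min 6.

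In menadione II at 51 to 90 min, 279 of 5537 genes changed, 120 up and 159 down. PRX1 rose by 4.02 ± 0.64, adjusted p = 0.000394 (4 arrays against 4) and ECM4 by 3.33 ± 0.90, adjusted p = 0.0271. The glutathione peroxidase family gene GPX2 rose by 2.99 ± 0.63, adjusted p = 0.00534, FLR1 by 2.98 ± 0.65, adjusted p = 0.00615 and TRR1 by 2.78 ± 0.62, adjusted p = 0.00697. Of 24 Yap1 list genes 13 rose, 19 when adjusted over the list alone. On average they stood at 1.89 ± 0.21 (adjusted p = 1.5e-17, and adjusted p = 0.0071 with an estimated correlation). ZWF1 and SOL3, for the first 2 steps of the pentose phosphate pathway, rose by 2.35 ± 0.52, adjusted p = 0.0069 and 2.40 ± 0.53, adjusted p = 0.00654, while RKI1, for ribose-5-phosphate ketol-isomerase, fell by 2.07 ± 0.63, adjusted p = 0.048. Of the 72 ribosomal protein genes 24 fell, 39 when adjusted over the list alone. RPS2 fell by 2.15 ± 0.32, adjusted p = 0.000227 and RPL20A fell by 2.14 ± 0.44, adjusted p = 0.00504. The mean change was -1.06 ± 0.069 (adjusted p = 6.47e-23, and adjusted p = 0.0071 with an estimated correlation). Of the ribosome biogenesis genes 9 of 40 fell, 16 when adjusted over the list alone. NOP1, for fibrillarin, fell by 2.48 ± 0.53, adjusted p = 0.00582. The mean was -1.13 ± 0.15 (adjusted p = 1.43e-09, and adjusted p = 0.113 with an estimated correlation). Of 43 G1/S genes 4 fell and 3 rose, DPB2 among the latter at 1.76 ± 0.48, adjusted p = 0.0279. The list mean was -0.45 ± 0.15 (adjusted p = 0.0311, and adjusted p = 0.42 with an estimated correlation). POL30, for PCNA, fell by 2.94 ± 0.62, adjusted p = 0.00552, the cyclin gene CLB5 fell by 2.02 ± 0.61, adjusted p = 0.0477 and DUN1, for a checkpoint kinase, fell by 2.04 ± 0.49, adjusted p = 0.0124. CLB1 was higher by 1.49 ± 0.35, adjusted p = 0.0104, and 2 of 30 CLB2 cluster genes rose, 4 when adjusted over the list alone. Their mean was 0.74 ± 0.13 (adjusted p = 4.59e-05, and adjusted p = 0.0201 with an estimated correlation). Of 35 general stress genes only HXK1 (3.17 ± 0.58, adjusted p = 0.00206) and YGP1 (4.03 ± 1.00, adjusted p = 0.0143) rose over all genes tested, and 3 when adjusted over the list alone. The list averaged 0.88 ± 0.17 (adjusted p = 5.85e-05, and adjusted p = 0.319 with an estimated correlation). The histidine gene HIS4 fell by 2.49 ± 0.46, adjusted p = 0.00206. Fitted with the arrays of these 2 windows alone the count was 73, and leaving out the 85 min array gave 135.

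After 90 min of menadione II, 160 of 5538 genes differed from the first 21 min, 67 up and 93 down. RPS2 fell by 2.24 ± 0.32, adjusted p = 0.000147 (4 arrays against 4), RPS20 fell by 2.26 ± 0.40, adjusted p = 0.00172 and RPS26A fell by 1.89 ± 0.43, adjusted p = 0.0113. In all 17 of 72 ribosomal protein genes fell, 43 when adjusted over the list alone. On average they stood at -1.07 ± 0.061 (adjusted p = 1.76e-25, and adjusted p = 0.00332 with an estimated correlation). Higher were PRX1 (3.77 ± 0.64, adjusted p = 0.00122), FLR1 (3.34 ± 0.65, adjusted p = 0.0039) and 4 more of the 24 Yap1 list genes, 16 when adjusted over the list alone. The mean change was 1.53 ± 0.21 (adjusted p = 1.91e-13, and adjusted p = 0.0225 with an estimated correlation). The pentose phosphate genes SOL3 (2.81 ± 0.53, adjusted p = 0.00269), GND1 (1.44 ± 0.36, adjusted p = 0.0233) and ZWF1 (1.95 ± 0.52, adjusted p = 0.0348) rose. These were 3 of 9 in the list, with 3 higher and 1 lower when adjusted over the list alone. The mean was 0.71 ± 0.42 (adjusted p = 0.00614, and adjusted p = 0.0218 with an estimated correlation). TIS11, an mRNA-decay factor gene of the iron regulon, fell by 3.68 ± 0.72, adjusted p = 0.00466, and MET32, a regulator of sulfur amino acid genes, rose by 2.99 ± 0.60, adjusted p = 0.00466. Leaving out the array of 14, 100, 130 or 140 min gave 74, 87, 98 and 87 genes, and fitting the arrays of these 2 windows alone gave 82. With other window edges the count was 277.

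At 51 to 90 min, 62 genes rose with both oxidants among 5517 tested in both, against 10.7 if the lists were independent (Fisher's exact p = 1.47e-34 across genes, which are not independent). Of genes that fell, 59 were shared against 8.01 for independent lists (Fisher's exact p = 1.92e-37). After 90 min, 1 gene was shared upward and 1 downward, against 0.34 and 0.118 for independent lists. Both courses follow cells released from G1 arrest, and no untreated course is named. The lists could overlap from cycle progress alone, so the sharing is not a measure of a common response to the oxidants.

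The study's title names both oxidants, and the direct question is where their effects differ. The difference of changes, peroxide II minus menadione II, was tested as an interaction in 1 model. A value called higher with peroxide can come from a rise with peroxide, a fall with menadione or both. The reverse holds for lower. At 22 to 50 min no gene of 5500 passed limma's test (smallest adjusted p = 0.0887), while 590 had an unadjusted p under 0.05 where chance gives 275. The means of 3 stress lists were higher with peroxide. They were Yap1 and thiol-redox genes, by 1.22 ± 0.24 (adjusted p = 0.000407), general stress genes, by 0.72 ± 0.14 (adjusted p = 0.0106) and proteasome genes, by 0.60 ± 0.16 (adjusted p = 0.00504). Each of the 3 had adjusted p = 0.689 with an estimated correlation. Cytosolic ribosomal proteins were lower, at -0.35 ± 0.087 (adjusted p = 0.00504, and adjusted p = 0.689 with an estimated correlation). The CLB2 cluster was lower with peroxide, at -0.65 ± 0.19, with 20 of 30 genes negative and 5 lower when adjusted over the list alone (adjusted p = 0.00136, and adjusted p = 0.222 with an estimated correlation). The cyclin gene CLB2 itself was not among the negative ones. In menadione II it was at 1.28 ± 0.45, adjusted p = 0.389, less than its rise in peroxide II given above. Differences of single genes in these lists were ECM4 at 4.06 ± 1.32, adjusted p = 0.241, CCP1 at 3.49 ± 1.14, adjusted p = 0.241, BUD3 at -2.23 ± 0.60, adjusted p = 0.206 and AIM20 at -2.29 ± 0.69, adjusted p = 0.22, 4 arrays per group. Within the first scan day of peroxide II, 19 genes differed and the means were 1.57 for the Yap1 list and -0.87 for the CLB2 cluster. Leaving out the 28 min peroxide array gave 82 genes.

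In the 51 to 90 min window 8 of 5517 genes differed, 6 of them higher with peroxide. The glycolytic gene TPI1, for triose phosphate isomerase, was higher by 2.91 ± 0.48, adjusted p = 0.00602 (4 arrays per group) and MSI1, for a chromatin assembly factor subunit, by 2.92 ± 0.52, adjusted p = 0.00816. YET3 was higher by 3.10 ± 0.62, adjusted p = 0.035 and SSL2, for a helicase of transcription and repair, by 3.13 ± 0.68, adjusted p = 0.0472. The transcription factor gene YAP5 was higher by 2.74 ± 0.57, adjusted p = 0.0421 and MAF1, for the repressor of RNA polymerase III, by 2.20 ± 0.46, adjusted p = 0.0421. VPS5, for a retromer subunit, differed by -4.29 ± 0.93, adjusted p = 0.0472 and YER137C by -2.31 ± 0.50, adjusted p = 0.0472. DNA damage genes were higher with peroxide by 1.07 ± 0.36 on average, 10 of 13 positive and 3 higher when adjusted over the list alone (adjusted p = 0.0122, and adjusted p = 0.305 with an estimated correlation). RNR2 was at 3.60 ± 0.86, adjusted p = 0.0503 and DUN1 at 2.85 ± 0.70, adjusted p = 0.0503. The proteasome list was higher by 0.84 ± 0.16 (adjusted p = 0.00182, and adjusted p = 0.371 with an estimated correlation) and the general stress list by 0.77 ± 0.20 (adjusted p = 0.0467, and adjusted p = 0.705 with an estimated correlation). The SIC1 cluster was lower, at -0.99 ± 0.25 (adjusted p = 0.0122, and adjusted p = 0.339 with an estimated correlation), with DSE3 at -2.45 ± 0.81, adjusted p = 0.133, and the CLB2 cluster was lower, at -0.51 ± 0.18 (adjusted p = 0.0124, and adjusted p = 0.339 with an estimated correlation). The change of the CLB2 gene itself was larger in peroxide II (2.14 ± 0.42, adjusted p = 0.00107) than in menadione II (0.67 ± 0.45, adjusted p = 0.435). Within the first scan day of peroxide II the DNA damage mean was 1.18, the SIC1 mean -1.57 and the general stress mean 0.49 (adjusted p = 0.105), and 10 genes differed. With scan day as a covariate 2 genes differed, TPI1 and MSI1. The others kept their direction. MAF1 was at 2.37 (adjusted p = 0.0567), SSL2 at 3.00 (adjusted p = 0.121) and VPS5 at -4.53 (adjusted p = 0.0758). YAP5 was at 2.25 (adjusted p = 0.121), YER137C at -2.01 (adjusted p = 0.129) and YET3 at 2.31 (adjusted p = 0.121). Some of these values grew in size and others shrank, so their loss neither shows nor excludes an effect of scan day. In that fit the general stress mean was 0.25 (adjusted p = 0.571). At times sampled in both courses with the time point as a block no gene differed. There the SIC1 mean was -0.67 (adjusted p = 0.0204). In this window 70 min has a peroxide array alone and 85 min, when the list was highest in menadione II, a menadione array alone. Leaving out single arrays gave 2 to 43 genes. Counts were 62 with array weights, 44 with other window edges, 31 with scaled arrays, 26 with genes measured in every array and 3 with the deposited values as given.

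After 90 min 60 of 5519 genes differed, 50 of them higher with peroxide. RNR2 and RNR4, small subunits of ribonucleotide reductase, were higher by 4.09 ± 0.84, adjusted p = 0.0291 and 3.38 ± 0.75, adjusted p = 0.0291 (5 peroxide and 4 menadione arrays after 90 min). CLB2 was higher by 3.20 ± 0.60, adjusted p = 0.0213, DSN1, for a kinetochore protein, by 3.70 ± 0.76, adjusted p = 0.0291 and MCM3, for a replicative helicase subunit, by 1.83 ± 0.48, adjusted p = 0.0495. The glycolytic genes TPI1 and CDC19, for pyruvate kinase, were higher by 2.15 ± 0.47, adjusted p = 0.0291 and 2.40 ± 0.59, adjusted p = 0.0413, the sterol gene ERG27 by 2.46 ± 0.58, adjusted p = 0.0319 and TIS11 by 4.86 ± 1.06, adjusted p = 0.0291. Ribosomal protein genes were higher with peroxide by 0.99 ± 0.094 on average (adjusted p = 1.36e-10, and adjusted p = 0.129 with an estimated correlation). Of the 72 genes 65 were positive and 3 passed the test over all genes, 14 when adjusted over the list alone, with RPS26A at 2.74 ± 0.59, adjusted p = 0.0291. DNA damage genes were higher by 1.17 ± 0.38 (adjusted p = 0.00947, and adjusted p = 0.129 with an estimated correlation) and S phase genes by 1.14 ± 0.41 (adjusted p = 0.0358, and adjusted p = 0.129 with an estimated correlation). Glycolysis genes were higher by 0.84 ± 0.23 (adjusted p = 0.00947, and adjusted p = 0.242 with an estimated correlation) and ergosterol synthesis genes by 0.78 ± 0.20 (adjusted p = 0.0189, and adjusted p = 0.153 with an estimated correlation). The ribosome biogenesis list was higher by 0.76 ± 0.18 (adjusted p = 0.0189, and adjusted p = 0.75 with an estimated correlation), and mating genes were at -0.49 ± 0.16 (adjusted p = 0.0299, and adjusted p = 0.75 with an estimated correlation). The pentose phosphate gene SOL3 was lower with peroxide, at -2.90 ± 0.72, adjusted p = 0.0434 and the membrane protein gene YRO2 at -2.59 ± 0.67, adjusted p = 0.0495. Large positive values were those of PUP3 (5.27 ± 1.15, adjusted p = 0.0291), BCK1, for a kinase of the cell wall pathway (4.73 ± 1.04, adjusted p = 0.0291), and IRC25 (4.68 ± 0.74, adjusted p = 0.00517).

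Within the first scan day of peroxide II, 23 genes differed after 90 min and the ribosomal protein mean was 1.12. With scan day as a covariate 10 genes differed and that mean was 1.12. CLB2, DSN1 and TIS11 still passed the test then, while RNR2 was at 3.40 (adjusted p = 0.0736), RNR4 at 2.80 (adjusted p = 0.0908), RPS26A at 2.20 (adjusted p = 0.0824), PUP3 at 4.03 (adjusted p = 0.0908) and TPI1 at 1.91 (adjusted p = 0.0821). MCM3 at 1.70 (adjusted p = 0.121), CDC19 at 2.03 (adjusted p = 0.125), ERG27 at 2.53 (adjusted p = 0.0736), SOL3 at -2.49 (adjusted p = 0.131) and BCK1 at 4.45 (adjusted p = 0.0803) did not pass either. All kept their direction, and all of these but ERG27 became smaller in size. FLR1, by contrast, went from -3.19 to -4.08 and passed with the covariate (adjusted p = 0.0368). The covariate is mixed with time, so the lost and gained calls neither show nor exclude an effect of scan day. With the deposited values uncentred the count was 241, with array weights 106, and at times sampled in both courses with the time point as a block no gene differed. Leaving out single arrays gave 3 genes (without the 140 min peroxide array) to 74 (without the 0 min menadione array).

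**Figure D1:**
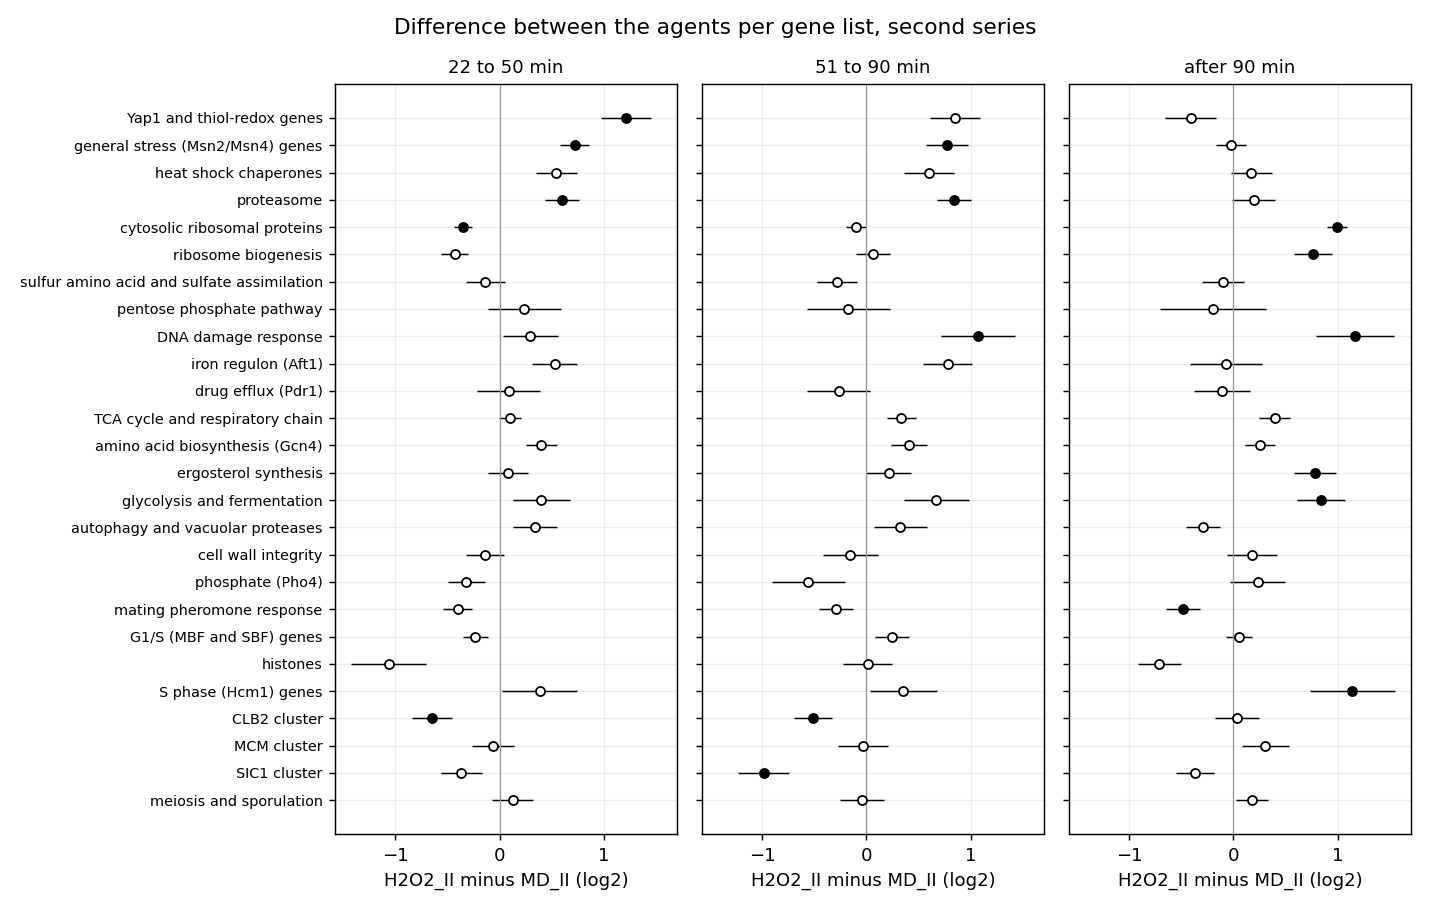
Difference between the oxidants in the change of each gene list from the first 21 min (peroxide II minus menadione II, mean log2 over the list's genes, horizontal axis) for the 26 lists, in the 3 windows; bars are SE over genes, and filled points have a camera adjusted p under 0.05 with the preset correlation of 0.01. The ribosomal protein list lies at -0.35 ± 0.087 in the first panel and at 0.99 ± 0.094 in the last, and no filled point keeps an adjusted p under 0.05 with an estimated correlation.

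The first series used both oxidants on other arrays and other cultures. In peroxide I at 22 to 50 min, 43 of 5548 genes changed, 28 up and 15 down (3 time points against 3). FLR1 rose by 3.72 ± 0.59, adjusted p = 0.00323, GRX2, for a glutaredoxin, by 3.06 ± 0.53, adjusted p = 0.00549 and DDR2 by 4.12 ± 0.82, adjusted p = 0.0176, and CLN2 fell by 2.62 ± 0.43, adjusted p = 0.00374. Of the 24 Yap1 list genes 3 rose, with 13 higher and 1 lower when adjusted over the list alone. On average they stood at 1.67 ± 0.25 (adjusted p = 5.5e-12, and adjusted p = 0.0382 with an estimated correlation). G1/S genes averaged -0.41 ± 0.10 (adjusted p = 5.61e-06, and adjusted p = 0.00503 with an estimated correlation). Of the 43 genes 3 fell, 6 when adjusted over the list alone, and CLB6 fell by 1.52 ± 0.27, adjusted p = 0.00549. The count was 3 with other window edges, and 14, 11, 25, 389, 16 and 11 without 0, 14, 20, 30, 40 and 49 min.

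At 51 to 90 min of peroxide I, 847 of 5551 genes changed, 363 up and 484 down (5 time points against 3). Ribosomal protein genes fell almost throughout, 68 of 72 and 70 when adjusted over the list alone. RPS22A fell by 3.01 ± 0.31, adjusted p = 6.11e-06 and RPL9A fell by 2.93 ± 0.52, adjusted p = 0.000509. The mean change was -2.01 ± 0.06 (adjusted p = 4.72e-57, and adjusted p = 0.0131 with an estimated correlation). General stress genes rose in 25 of 35 cases, 29 when adjusted over the list alone. DDR2 rose by 6.09 ± 0.74, adjusted p = 3.48e-05 and YGP1 by 4.68 ± 0.52, adjusted p = 1.56e-05. The mean was 2.19 ± 0.24 (adjusted p = 7.55e-23, and adjusted p = 0.0131 with an estimated correlation). Of 24 Yap1 list genes 18 rose, 19 when adjusted over the list alone. PRX1 rose by 4.26 ± 0.86, adjusted p = 0.00153 and GPX2 by 4.25 ± 1.01, adjusted p = 0.00534. Their mean was 2.11 ± 0.26 (adjusted p = 4.47e-12, and adjusted p = 0.0162 with an estimated correlation). Vacuolar and autophagy genes rose in 8 of 15 cases, 10 when adjusted over the list alone. ATG8 rose by 2.91 ± 0.48, adjusted p = 0.000266 and the protease gene PEP4 by 2.01 ± 0.37, adjusted p = 0.00072. The list averaged 1.11 ± 0.22 (adjusted p = 9.01e-07, and adjusted p = 0.00522 with an estimated correlation). Ribosome biogenesis genes fell in 24 of 40 cases with 1 rise, 32 lower and 1 higher when adjusted over the list alone. NSR1 fell by 3.46 ± 0.52, adjusted p = 0.000142. On average they stood at -1.43 ± 0.14 (adjusted p = 3.72e-19, and adjusted p = 0.0162 with an estimated correlation). Heat shock chaperone genes rose in 12 of 19 cases, 14 when adjusted over the list alone. The mean change was 1.06 ± 0.15 (adjusted p = 1.28e-07, and adjusted p = 0.0585 with an estimated correlation). Of 22 iron list genes 6 rose, 9 when adjusted over the list alone, and their mean was 0.81 ± 0.19 (adjusted p = 0.00054, and adjusted p = 0.0192 with an estimated correlation). The histone gene HTA1 fell by 2.80 ± 0.73, adjusted p = 0.00983, HTA2 fell by 2.39 ± 0.60, adjusted p = 0.00763 and CLN2 fell by 2.33 ± 0.39, adjusted p = 0.000308. CLB2 was at -0.125 ± 0.294, adjusted p = 0.852, so its rise in peroxide II was not repeated here.

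In menadione I at 22 to 50 min (2 arrays against 3) no gene of 5498 passed limma's test, with 174 at an unadjusted p under 0.05 where chance gives 274.9. The CLB2 cluster had a mean of 0.88 ± 0.15, 26 of 30 genes positive and 3 higher when adjusted over the list alone (adjusted p = 4.01e-10, and adjusted p = 4.43e-07 with an estimated correlation), and CLB2 itself was at 2.99 ± 0.69, adjusted p = 0.822. At 51 to 90 min of menadione I, 106 of 5552 genes changed, 68 up and 38 down (4 arrays against 3). GTT2, a glutathione transferase gene, rose by 4.71 ± 0.49, adjusted p = 4.72e-05, GPX2 by 4.83 ± 0.60, adjusted p = 4e-04, AAD14 by 5.21 ± 0.93, adjusted p = 0.0086 and GRE2 by 5.15 ± 0.67, adjusted p = 0.000635. Of 24 Yap1 list genes 15 rose, 19 when adjusted over the list alone. The mean was 2.43 ± 0.31 (adjusted p = 5.36e-34, and adjusted p = 4.19e-10 with an estimated correlation). General stress genes rose in 6 of 35 cases, 19 when adjusted over the list alone (mean 1.46 ± 0.17; adjusted p = 1.23e-15, and adjusted p = 0.0076 with an estimated correlation), and PST1, a cell wall gene, rose by 3.55 ± 0.50, adjusted p = 0.00124. Ribosomal protein genes fell in 9 of 72 cases, 36 lower and 1 higher when adjusted over the list alone. RPS21A fell by 2.51 ± 0.51, adjusted p = 0.019. Their mean was -1.17 ± 0.073 (adjusted p = 4.84e-26, and adjusted p = 0.00391 with an estimated correlation). The SIC1 cluster averaged 0.83 ± 0.17 (adjusted p = 0.00016, and adjusted p = 0.0491 with an estimated correlation). Of its 18 genes 1 rose, 5 when adjusted over the list alone, and RME1 rose by 1.97 ± 0.42, adjusted p = 0.0234. Leaving out the array of 0, 14, 20, 70 or 85 min gave 70, 32, 33, 40 and 48 genes, and array weights gave 247.

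Across the 5472 genes measured in both peroxide courses, the changes at 22 to 50 min had a Pearson r of 0.425 and a Spearman rho of 0.339, and of the 217 genes called in peroxide II 189 (87.1%) had the same sign in peroxide I (r = 0.755), while 13 were called in both. Over all genes 60.3% had the same sign. For the 51 to 90 min window r was 0.584 over 5493 genes, 65.1% had the same sign, and 316 genes were called in both courses. For menadione r was 0.136 over 5460 genes at 22 to 50 min and 0.478 over 5512 genes at 51 to 90 min, where 250 of 278 genes called in menadione II (89.9%) had the same sign in menadione I and 45 were called in both, against 64% with the same sign over all genes. These correlations are across genes, which are not independent replicates.

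List means were also followed over the times of each course, where highest and lowest points were described and not tested. Yap1 and thiol-redox genes stood at 0.65 ± 0.23 at 28 min of peroxide II and at 2.32 ± 0.31 at 35 min, were highest at 70 min (3.00 ± 0.41) and had come down to 0.37 ± 0.23 at 180 min. In peroxide I they were highest at 55 min (2.97 ± 0.34) and at 0.11 ± 0.10 by 190 min. In menadione II the list was at -0.20 ± 0.21 at 28 min, highest at 56 min (2.13 ± 0.28; at 85 min by the median of its genes) and at 1.59 ± 0.25 at 130 min. In menadione I it was highest at 170 min (2.775; at 120 min by the median of its genes) and at 2.58 ± 0.39 at 210 min, the last time. Ribosomal protein genes of peroxide II were at -1.40 ± 0.11 at 56 min and at 0.029 ± 0.077 at 120 min. In peroxide I they were at -2.38 ± 0.065 at 77 min and -0.32 ± 0.041 at 120 min. In menadione II they stood at -1.26 ± 0.089 at 77 min and -1.12 ± 0.075 at 140 min, and in menadione I at -1.40 ± 0.085 and -0.58 ± 0.094 at those times. Levels of the first series come from separate tables and were not tested against those of the second. Arrays repeated at 63 min of peroxide I had mean levels of ribosomal protein genes of -2.74 and -1.24 and of the Yap1 list of 1.39 and 1.85. The ribosomal protein values given for peroxide II and for both menadione courses lie closer together than those repeats, and no turn is read from them.

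**Figure D2:**
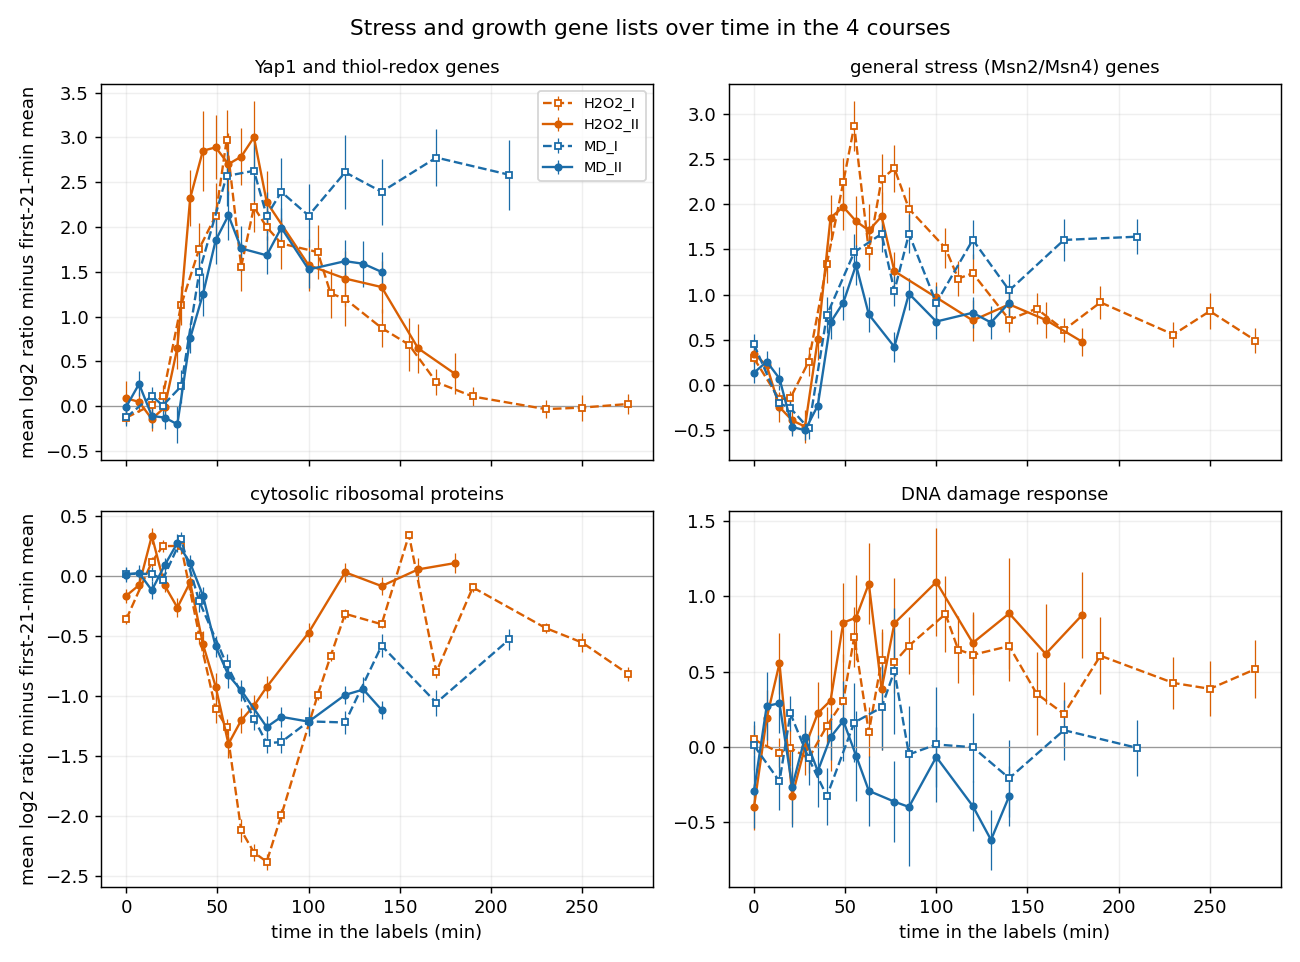
Mean log2 ratio of 4 gene lists minus the mean of the first 21 min (vertical axis) against the time in the labels in min (horizontal axis), for peroxide (orange) and menadione (blue) in the first series (dashed, open squares) and the second (solid, filled circles); bars are SE over genes, and repeated arrays of 1 time are averaged. Ribosomal protein genes of peroxide II stood at -1.40 ± 0.11 at 56 min and at 0.029 ± 0.077 at 120 min, whereas those of menadione II stood at -1.12 ± 0.075 at 140 min.

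Of the cell cycle lists, G1/S genes were highest at 14 min, at 0.18 ± 0.046, 0.80 ± 0.12, 0.46 ± 0.082 and 0.53 ± 0.11 in peroxide I, peroxide II, menadione I and menadione II. Histone genes were highest at 20 or 21 min in peroxide I and II and menadione I, and at 28 min in menadione II (2.20 ± 0.46). In the order of the G1/S values, the S phase list was highest at 250, 100, 77 and 85 min and the MCM cluster at 0, 7, 140 and 7 min. No untreated course is given in the labels used here. The CLB2 cluster was highest at 40 min in menadione I (0.93 ± 0.18) and at 56 min in menadione II (1.01 ± 0.20), while at 55 and 56 min of peroxide I and II it was at -0.084 ± 0.16 and -0.084 ± 0.20 and its highest values came at 250 and 180 min (0.67 ± 0.11 and 0.76 ± 0.15). The SIC1 cluster, which follows it in an undisturbed cycle, was highest at 70 min in menadione I (1.06 ± 0.23) and at 85 min in menadione II (0.76 ± 0.32), after a low at 56 min (-1.46 ± 0.63). In peroxide II it was at -1.08 ± 0.41 at 77 min, and in peroxide I it was lowest at 49 min (-0.81 ± 0.28) and highest at 275 min (0.65 ± 0.14). Arrays repeated at the same time differed by at most 0.16 for the CLB2 cluster and 0.37 for the SIC1 cluster, and by 0.43 and 1.73 for histones. Turning times were described and not tested, and 73 of 208 moved under alternatives.

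**Figure D3:**
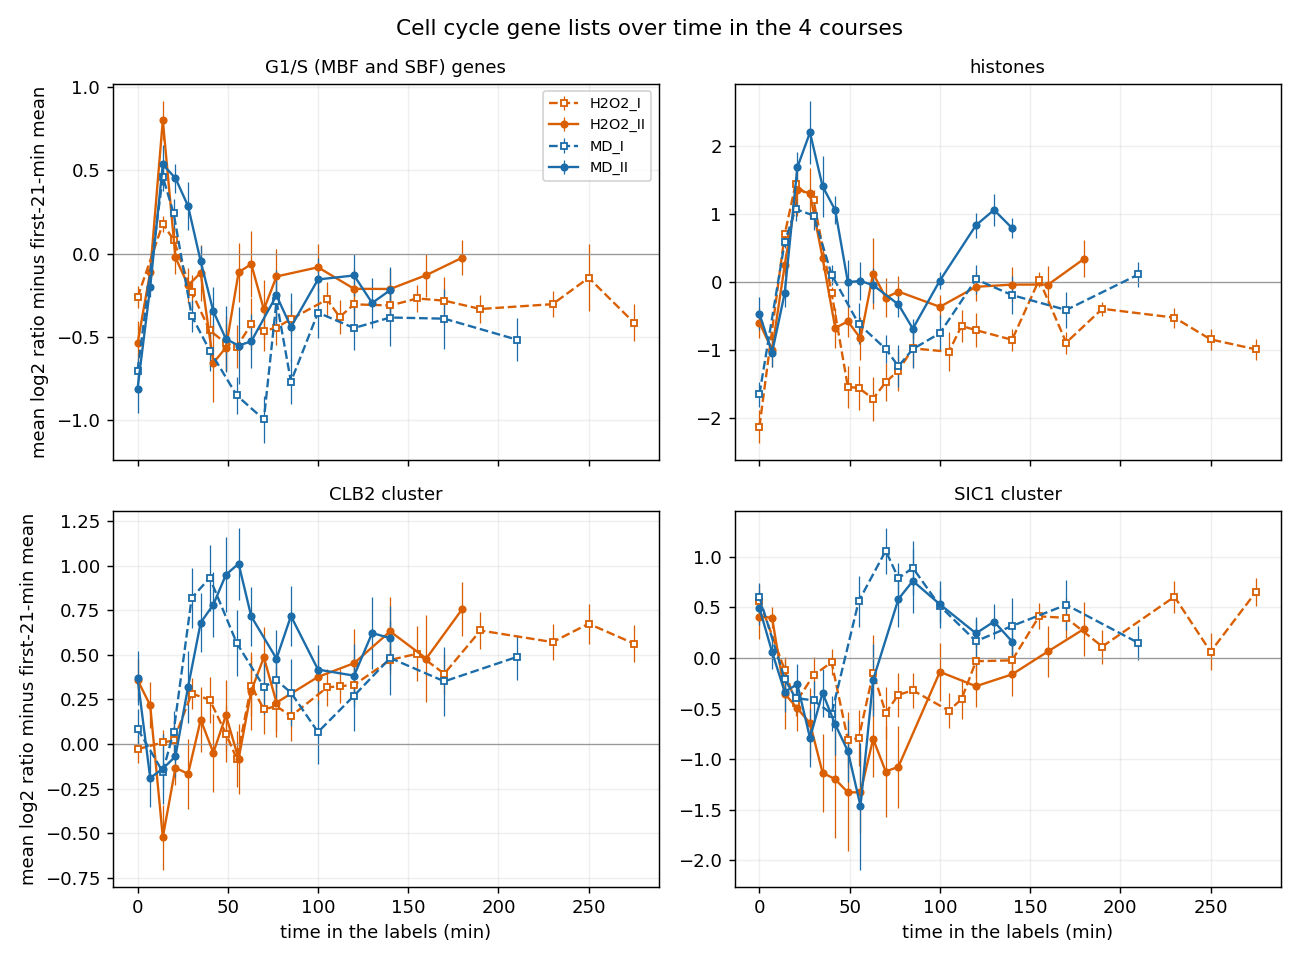
Mean log2 ratio of 4 cell cycle gene lists minus the mean of the first 21 min (vertical axis) against the time in the labels in min (horizontal axis), for peroxide (orange) and menadione (blue) in the first series (dashed, open squares) and the second (solid, filled circles); bars are SE over genes, and repeated arrays of 1 time are averaged. The CLB2 cluster reached 0.93 ± 0.18 at 40 min of menadione I and 1.01 ± 0.20 at 56 min of menadione II, and stood at -0.084 ± 0.20 at 56 min of peroxide II.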

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

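The fits without the 14 and 42 min peroxide II arrays, the comparison of ribosomal protein genes at matched times and the fits within a scan day were tests chosen after results were seen. The 3 patterns weighed were also picked from the results, and what their other tests would show was written down before those tests were run. A test for arrays standing apart from their window picked out 8 arrays in 156 tests, where chance gives about 1 in 20. Missing spots stood apart at 77 min of menadione I (14.5%, nearest 8.5%), 20 min of peroxide I (7.1%, nearest 5%), 42 min of peroxide II (26.9%, nearest 9.4%), 140 min of peroxide II (4.8%, nearest 1.9%) and 28 min of menadione II (6.5%, nearest 2.9%). The array median stood apart at 63 min (0.22, nearest 0.021) and 170 min (0.12, nearest 0.043) of peroxide I. That of 63 min is the first of a pair, and that of 170 min is labelled a redo without a partner here. The 49 min array, 1 of 3 at 22 to 50 min of peroxide I, is likewise a redo without a partner. General stress genes at 0 min of peroxide I averaged 0.23 against -0.19 in the nearest array.

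The interaction test called 8 genes at 51 to 90 min and 60 after 90 min, and these lists differed between the oxidants with the preset correlation but none with an estimated correlation. At 22 to 50 min the mean differences were 1.22 for Yap1 and thiol-redox genes, 0.72 for general stress genes, 0.60 for proteasome genes, -0.35 for ribosomal proteins and -0.65 for the CLB2 cluster. In the 51 to 90 min window they were 0.77 for general stress genes, 0.84 for the proteasome, 1.07 for DNA damage genes, -0.51 for the CLB2 cluster and -0.99 for the SIC1 cluster. After 90 min they were 0.99 for ribosomal proteins, 0.76 for ribosome biogenesis, 1.17 for DNA damage genes, 0.78 for ergosterol synthesis, 0.84 for glycolysis, -0.49 for mating genes and 1.14 for S phase genes.

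Probes without a gene name in the annotation, 8406 in the second series, also changed. In peroxide II 115, 586 and 25 passed the threshold in the 3 windows in turn, in menadione II 3, 128 and 143, and in the difference 3 at 51 to 90 min and 21 after 90 min. At 22 to 50 min no such probe passed limma's test of the difference.

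CLB2 cluster genes were on average lower with peroxide than with menadione at 22 to 50 min (-0.65), though the CLB2 gene itself was not. Scan day and sparse arrays could each give this, but with the scan day as a covariate the mean was -0.75 ± 0.18 (adjusted p = 0.000232), and without the sparse 14 and 42 min arrays -0.80 ± 0.18 (adjusted p = 5.83e-05). In peroxide II the cluster was lowest at 14 min (-0.522), so leaving that array out raises the baseline and lowers the difference. The fit without the sparse arrays therefore cannot decide about them. The second scan day of peroxide II held only 14, 21 and 28 min. The covariate is therefore mixed with time and cannot decide about scan day. Within the first scan day alone the mean kept its direction, as given above. There the baseline of peroxide II is 0 and 7 min only, without the low 14 min array. That fit changes the baseline times along with the scan day, so it cannot decide about scan day either. Chance is not excluded, since 7 of 100 splits of the arrays, the real one among them, gave a mean difference as large in either direction (highest other 0.82), and the adjusted p with an estimated correlation was 0.222. A different pace of the cycle or a different agent effect stays open and was not tested.

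DNA damage genes were higher with peroxide at 51 to 90 min (1.07), though not with an estimated correlation (adjusted p = 0.305). Without RNR2, RNR3 and RNR4 the other 10 members averaged 0.73 ± 0.36, 7 of them positive, which is barely more than 2 SE above 0 and argues weakly against those 3 genes as the only source. With the scan day as a covariate the mean was 1.04 ± 0.35 (adjusted p = 0.00559). That covariate is mixed with time and cannot decide about scan day here either. Within the first scan day alone the mean kept its direction, as given above. That fit leaves only 0 and 7 min as the peroxide II baseline, so it cannot decide about scan day. Of 100 splits 2, the real one among them, gave a mean as large (highest other 1.08). The list was picked from 26 for its difference in these same data, so this share does not exclude chance. The difference may reflect the agents or the cycle stage of the cells, and neither was tested apart from the other.

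Ribosomal protein genes were higher with peroxide after 90 min (0.99), though not with an estimated correlation (adjusted p = 0.129). Late arrays were taken at different times, but over the times sampled in both courses the mean was 0.94 ± 0.095 (adjusted p = 2.02e-09). With the scan day as a covariate it was 1.12 ± 0.084 (adjusted p = 4.24e-15), a fit that cannot decide about scan day, because the covariate is mixed with time. Within the first scan day alone the mean kept its direction, as given above. That fit has only 0 and 7 min as the peroxide II baseline and cannot decide about scan day either. Of 100 splits only the real one gave a mean as large (highest other 0.89), though this list too was picked from the results. One culture per agent and unstated doses in the second series keep agent, dose and culture from being told apart, so that an earlier recovery from peroxide remains a hypothesis. Repeated arrays at 63 min of peroxide I differed in this list by more than the pattern itself.

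Other splits of the arrays into groups of the same sizes were counted for every comparison with at least 3 arrays per group. For genes in peroxide II at 22 to 50 min, 4 of 35 splits gave as many as the real 217, the highest other 386, so chance is not excluded there. The splits with 386, 320 and 262 genes all put 28 min with early arrays and 1 early array (0, 7 and 14 min in turn) with 35, 42 and 49 min. Such splits keep much of the early against late order, so they cannot decide about chance. Those with 386 and 320 have all 3 arrays of the second scan day on 1 side. Within the first scan day 328 genes changed and within the second 10, but there 1 array stands for the later window, so that the second value tells nothing about scan day. In the 51 to 90 min window of peroxide II only the real split of 35 reached 774 (highest other 3), and after 90 min only the real 1 of 100 reached 35 (highest other 7). In menadione II all 35 splits gave at least the real 0 at 22 to 50 min (highest other 8), while 1 of 35 reached 279 (highest other 6) and 1 of 35 reached 160 (highest other 2) in the later windows. For the difference all 100 splits gave at least the real 0 at 22 to 50 min (highest other 72), while 1 of 100 reached 8 (highest other 5) and 1 of 100 reached 60 (highest other 3) later. These splits ignored the times sampled in both courses. With those times as a block no gene differed in either later window. For peroxide I at 22 to 50 min 10 splits are too few for a share under 0.05 (43 genes, highest other 16, and 14 lists, highest other 14, with 1 and 2 splits as large). Only the real split reached 847 genes in peroxide I at 51 to 90 min (1 of 56, highest other 227). The same held for 106 in menadione I (1 of 35, highest other 11). Time points of 1 culture are ordered, and within a course the real split sets early against late ones. Any steady change over time makes that split the largest, so the shares within a course cannot tell a response from other changes of the culture. For the difference, arrays were exchanged between peroxide II and menadione II, within the window and within the baseline. There any difference between the courses in their change over time can make the real split the largest. Those shares cannot tell the agent from dose, culture or scan day.

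The number of lists shifted with the preset correlation was less specific than the number of genes. Splits as large as the real one, which is counted among them, numbered 7 of 35 (real 11, highest other 12), 6 of 35 (11 and 11) and 15 of 100 (6 and 10) in the peroxide II windows. In menadione II they numbered 2 of 35 (10 and 10), 1 of 35 (13 and 12) and 6 of 35 (8 and 9), and in the difference 45 of 100 (5 and 13), 32 of 100 (5 and 9) and 13 of 100 (7 and 9). For peroxide I at 51 to 90 min they numbered 10 of 56 (16 and 19), and for menadione I 5 of 35 (12 and 16). Only at 51 to 90 min of menadione II was the real list count the largest, at 13 against 12. Among this many list counts, 1 such result does not exclude chance.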

How the results depend on the processing

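The fits without the 14 and 42 min peroxide II arrays and those within 1 scan day were tests chosen after the data were seen, as were list counts with scaled arrays, without 0 min, over shared times and with the scan day as a covariate. The other alternatives were planned. Over all alternatives, named genes kept direction and side of the threshold in 17067 cases, became weaker in 624, stronger in 365 and reversed in 2; leaving out 1 array these were 15348 the same, 805 weaker and 225 stronger. Single lists stayed the same in 2010 cases, became weaker in 202, stronger in 68 and reversed in 8, and 73 of 208 times of highest or lowest list means moved. The causes below were not tested, except where fewer arrays or genes were used. No paired analysis was possible by replicate number, because the labels give none shared between courses, and times sampled in both courses served as a block instead. Signal over background was not given, so what it limits is unknown.

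With scan day as a covariate the counts were 126 and 202 and 6 in the 3 windows of peroxide II and 2 and 10 in the difference at 51 to 90 and after 90 min, with 11 lists after 90 min. The first scan day alone gave 328, 365 and 22 genes in peroxide II and 19 and 23 in the difference at 22 to 50 and after 90 min, with 8 lists at 22 to 50 min. The second day alone has 1 array (28 min) in the later window, so its values and changes of sign weigh neither for nor against an effect of scan day. It gave 10 genes and 2 lists in peroxide II and 0 lists in the difference. Its 10 genes shared 1 with the 217. It reversed general stress (-0.33, adjusted p = 0.348), proteasome (-0.21, adjusted p = 0.44) and ribosome biogenesis (0.19, adjusted p = 0.728) in peroxide II, IQG1 (0.090, adjusted p = 0.997) and NSR1 (0.032, adjusted p = 0.998), and in the difference Yap1 (-0.26, adjusted p = 0.42), general stress (-0.47, adjusted p = 0.262) and proteasome (-0.23, adjusted p = 0.42). Histones after 90 min of peroxide II reversed to 0.76 with the covariate (adjusted p = 0.0188) and to 0.76 on the first day alone (adjusted p = 0.0379). Both fits mix scan day with the times of the baseline, so this reversal cannot decide about scan day. Without the 14 and 42 min arrays peroxide II at 22 to 50 min gave 48 genes and the difference at 51 to 90 min 32, with 3 lists in the difference at 22 to 50 min.

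The deposited values as given shifted the median of all genes by up to 0.41 in the difference after 90 min (0.063 centred), and gave 83 genes in peroxide II after 90 min and 3 and 241 in the difference at 51 to 90 and after 90 min. Scaling arrays to the same spread gave 126 genes in peroxide II after 90 min, 88 in menadione II and 31 in the difference at 51 to 90 min, 68 in menadione I, and 8 lists in the difference at 51 to 90 min. Array weights gave 64 in peroxide II after 90 min, 62 and 106 in the later differences and 247 in menadione I. Window edges of 21, 43 and 80 min gave 85 in peroxide II at 22 to 50 min, 277 in menadione II after 90 min, 44 in the difference at 51 to 90 min, 3 in peroxide I at 22 to 50 min and 58 in menadione I. Fits with only the arrays of the groups compared gave 15 and 20 in peroxide II at 22 to 50 and after 90 min, 73 and 82 in menadione II at 51 to 90 and after 90 min and 3 in the difference at 51 to 90 min. Genes with a value in every array gave 6 in menadione II and 1 in the difference at 22 to 50 min and 26 in the difference at 51 to 90 min. Leaving the 0 min array out of the baseline gave 2 in menadione II at 22 to 50 min, 17 in the difference at 51 to 90 min, 14 in peroxide I at 22 to 50 min, 70 in menadione I and 3 lists in the difference after 90 min. Shared times with the time point as a block gave 0 and 0 genes in the later differences, and 9 and 9 lists in the earlier ones. A robust fit with a trend gave 25 in peroxide I at 22 to 50 min. With no change of fit, the correlation of the peroxide courses at 22 to 50 min was 0.755 over the genes called in peroxide II, against 0.425 over all genes.

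With an estimated correlation, lists called numbered 1, 3 and 0 in peroxide II, 2, 3 and 3 in menadione II, 0, 0 and 0 in the differences, 2 and 7 in peroxide I and 1 and 5 in menadione I. The fry test called 2 in menadione II, 0 in the difference, 9 in peroxide I and 1 in menadione I at 22 to 50 min and 1 in the difference at 51 to 90 min.

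Leaving out each array in turn gave 69 to 696, 495 to 697 and 16 to 57 genes in peroxide II, 0 to 10, 135 to 235 and 74 to 169 in menadione II, and 0 to 82, 2 to 43 and 3 to 74 in the difference. It gave 11 to 389 and 597 to 968 in peroxide I and 0 to 1 and 32 to 96 in menadione I. Counts moved by more than 1.5 times in peroxide II without 14 (122), 28 (696), 42 (69) or 49 min (81), without 56 min (495), and without 7 (57), 100 (17), 120 (16) or 140 min (16). In menadione II this held without 0 (3), 7 (1), 14 (2), 21 (6), 28 (10), 35 (3) or 42 min (1), without 85 min (135), and without 14 (74), 100 (87), 130 (98) or 140 min (87). For the difference at 22 to 50 min it held without peroxide 21 (3), 28 (82) or 35 min (2) and menadione 14 (1) or 21 min (3). At 51 to 90 min it held without peroxide 7 (18), 21 (4), 56 (3), 63 (2), 70 (2) or 77 min (14) and menadione 0 (43), 7 (3), 14 (4), 21 (18), 56 (16) or 77 min (2). After 90 min it held without peroxide 14 (33), 21 (19), 100 (39), 120 (27), 140 (3), 160 (34) or 180 min (33) and menadione 7 (30), 14 (18), 100 (28), 120 (26) or 130 min (25). In peroxide I it held without 0 (14), 14 (11), 20 (25), 30 (389), 40 (16) or 49 min (11), and in menadione I without 30 (1) and 0 (70), 14 (32), 20 (33), 70 (40) or 85 min (48).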

Other observations

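The mean of the histone genes stood higher again late in menadione II, though no test of it passed. With the first 21 min as 0 it was 2.20 ± 0.46 at 28 min, -0.69 ± 0.15 at 85 min and 0.83 ± 0.18, 1.06 ± 0.24 and 0.79 ± 0.15 at 120, 130 and 140 min. In peroxide II it was -0.074 ± 0.21 at 120 min and -0.041 ± 0.26 at 140 min, but its mean after 90 min turned from -0.037 ± 0.21 to 0.76 with the scan day as a covariate (adjusted p = 0.0188) and to 0.76 on the first scan day alone (adjusted p = 0.0379). The second scan day held the baseline arrays of 14 and 21 min. Within peroxide II the list was lowest at 7 min (-0.999) and highest at 21 min (1.357). Both fits mix scan day with these times, so the turn cannot decide about scan day. Over the window after 90 min the mean in menadione II was 0.68 ± 0.13 (adjusted p = 0.112, and adjusted p = 0.546 with an estimated correlation), with 9 of 9 genes positive and none past the threshold. The difference between the oxidants was -0.71 ± 0.21 (adjusted p = 0.156), so that none was shown. Repeated arrays at 63 min of peroxide I differed by 1.73 in this list, which is more than the late values.

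Some genes of respiration rose at 51 to 90 min, while the list as a whole was called with the preset correlation alone. In peroxide II CYC1 rose by 4.17 ± 0.67, adjusted p = 0.000156 and IDH2 by 2.72 ± 0.57, adjusted p = 0.00188, and of the 39 genes of the citric acid cycle and respiratory chain 6 rose and 1 fell. The list mean was 0.62 ± 0.14 (adjusted p = 0.00634, and adjusted p = 0.132 with an estimated correlation). In peroxide I CYC1 rose by 3.58 ± 0.82, adjusted p = 0.00381, IDH2 by 2.43 ± 0.47, adjusted p = 0.0011 and IDH1 by 2.15 ± 0.45, adjusted p = 0.00205, 10 genes rose, and the mean was 0.75 ± 0.12 (adjusted p = 1.32e-06, and adjusted p = 0.243 with an estimated correlation). In menadione II members went both ways, with CYC1 at 2.73 ± 0.67, adjusted p = 0.0136, ATP1 at 1.31 ± 0.33, adjusted p = 0.0181 and COX9 at -2.02 ± 0.38, adjusted p = 0.00226, and the mean was 0.28 ± 0.11 (adjusted p = 0.0465, and adjusted p = 0.319 with an estimated correlation). In menadione I 1 gene rose, and the mean was 0.56 ± 0.097 (adjusted p = 0.00023, and adjusted p = 0.092 with an estimated correlation).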
